A study of Homo sapiens and Mus musculus with 18 samples.

How the data were processed

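Poly-A RNA was sequenced from human cells made from the WA09 embryonic stem cell line and from sorted mouse cells. The human groups were MesoT (mesothelium made from splanchnic mesoderm with WNT3A, BMP4 and retinoic acid) at day 18 and day 22, MesoT kept in serum medium to passage 4 (MesoT FCS), mesothelium-like cells (MLC) made from splanchnic mesoderm with a TGF-beta receptor inhibitor and retinoic acid, MLC made by replating MesoT (MesoT-derived MLC), and smooth muscle made from splanchnic mesoderm. Per the labels, the serum medium of MesoT FCS also held FGF2. MesoT-derived MLC were given the TGF-beta receptor inhibitor and retinoic acid, with no WNT3A or BMP4 listed. The smooth muscle group held 1 library and each other human group 2. Mouse cells were tdTomato-positive Wt1-lineage cells of embryonic heart, lung, liver and gut, with 1 library per organ. Tamoxifen was given from embryonic day 12.5. Of the 18 samples, 15 had counts used here, and the 3 chromatin immunoprecipitation samples were not analysed here.

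The deposited values were whole-number counts per Ensembl gene ID. Per the submitters' processing notes, TopHat2 2.0.13, Bowtie2 2.2.9, Subread 1.4.2, featureCounts, MACS2 2.1.1 and the build hg19 were used, with no roles stated. The annotation release, the strand setting of the counting, the mouse build and the platform of each sample are not given in the sources used here. Read lengths and sequencers differed within the series, without a statement per sample. The 7 one-library files held MesoT day 18, MesoT FCS, MLC and smooth muscle, and a human table held MesoT day 18, day 22 and MesoT-derived MLC in 6 columns. The one-library files listed 63677 gene IDs, of which 52181 had a symbol in the reference of gene names, the human table listed 56299, of which 46802 had one, and 53243 IDs were in both. None of the 37991 mouse IDs had one, since the reference pairs human genes only, so the fixed mouse gene lists and the planned human to mouse rank correlation were not run. IDs with no symbol took between 0.834% and 1.52% of human counts and stayed in the library sizes and tests.

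Total counts are given with the results. A gene with 0 counts in a group was given a bound of 3 counts over the group, and a ratio resting on 1 to 3 counts a 95% exact binomial counting interval; both cover counting error only. MesoT day 18 was in both human sets, with unequal counts for the same labelled samples. The set was therefore marked of genes with at least 10 counts on average at day 18 in either set whose normalised day 18 counts lay within 0.5 log2 of each other in both replicates. These genes are called counted alike. Genes near 0 at day 18 cannot be in that set. The label does not cover the counting of other groups.

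Differential expression was computed with edgeR 4.0.16 in R 4.3.3 on the deposited counts (TMM scaling, filterByExpr by group, quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05). Comparisons within the one-library files were fitted over all 7 libraries, those within the human table over its 6 libraries, and MLC against MesoT-derived MLC over the IDs in both sets. Residual degrees of freedom were 3, or 5 for the last fit. The lone smooth muscle library was assumed to vary like the other groups. Errors of log2 fold changes are standard errors derived from the F statistic, and errors of CPM (counts scaled to library sizes of 1e6) are standard deviations over libraries. For each comparison 32 gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over the lists), and again with an estimated correlation. That estimate shifts somewhat with the order of the groups, alphabetical here. A higher p there need not reflect correlation: the estimate was -0.0178 for junction genes in MesoT FCS, under the preset. Principal components used log2 CPM with a prior count of 2 over the 1000 most variable genes. Mouse organs had no test: the log2 ratio of one organ to the mean of the others was computed from TMM-scaled CPM. Figures were drawn with matplotlib 3.10.9.

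The comparisons, tests, gene lists, alternative settings and rule for naming genes were fixed before the data were examined. The rule names the 6 highest and 6 lowest log2 fold changes among genes past the threshold with a mean log2 CPM of at least 3, no overlap between the libraries of the groups and a symbol that is not mitochondrial, ribosomal, pseudogene-style or clone-style, then up to 4 members of each described list by smallest p, and always WT1, UPK3B, MSLN, CDH1, KRT19, ACTA2, COL1A1, VIM and TCF21. A few genes that meet this rule are not described here, and no other gene took their place. The symbol filter at first also removed real genes whose symbols end in P and a digit or begin with LINC. It was corrected after values were seen, which named MMP1 in place of LGALS1 for MesoT FCS and LINC02593 in place of DES for the comparison of MLC routes. Which lists are described with examples was chosen after the list tests were seen, as were the lists of abundant liver transcripts, endoderm factors and stratified epithelium genes and the H19, DLK1, NNAT, IGF2 and MEG3 values. The fits on genes counted alike, the test of the difference between MLC routes through MesoT day 18, and the fits without the smooth muscle library were also added after the data were seen.

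Alternatives were DESeq2 1.42.0, limma voom, size factors by relative log expression, no low-count filter, only the groups compared, each library left out in turn, the replicate number as a block, and MesoT day 18 counts from the other set. Each fit was tested on simulated counts with 200 genes changed, 100 by 2-fold and 100 by 8-fold. For MLC against MesoT day 18, 78% of the 8-fold and 0% of the 2-fold changes were recovered among 23049 genes, with 13 false among 91 calls, so false calls there exceeded the nominal rate. For MesoT-derived MLC against MesoT, 88% and 6% were recovered among 22316 genes, with 8 false among 102 calls. For the lone smooth muscle library, 64% and 0% were recovered among 23049 genes, with 4 false among 68 calls. For MesoT day 22 against day 18, 82% and 1% were recovered among 22316 genes, with 5 false among 88 calls. False calls were 6 among 83 for MesoT FCS against MesoT day 18 and 6 among 84 for MLC against MesoT FCS. For MLC against MesoT-derived MLC they were 9 among 96. The share of false calls thus lay above the nominal rate in each fit, by little in some. The replicates are not stated to be separate cultures, so p-values measure the spread between these samples only, which may be technical.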

Results

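The data were gene counts from 11 human libraries and 4 mouse libraries. The series set an epithelial form of mesothelium beside a mesenchymal one, with smooth muscle as a comparison cell type. MesoT day 18 had totals of 28982850 and 22549057 counts in the one-library files and 30389378 and 24137663 in the human table. MesoT FCS had 27387053 and 21148477, MLC 70679258 and 65709545 and smooth muscle 27125377. MesoT day 22 had 29278721 and 24664507, and MesoT-derived MLC 31433961 and 31435480. The mouse libraries had 31502905 counts for heart, 21541758 for lung, 27398932 for liver and 28752101 for gut. Among the markers followed throughout were WT1 (ENSG00000184937), a transcription factor of mesothelium, UPK3B (ENSG00000243566) and MSLN (ENSG00000102854), which encode mesothelial surface proteins, and TCF21 (ENSG00000118526), a factor of coelomic mesenchyme. CDH1 and KRT19 stood for epithelial cells and ACTA2, COL1A1 and VIM for mesenchymal cells. In what follows, log2 fold changes carry their standard error and CPM values their SD with n = 2 libraries per group, except n = 1 for smooth muscle and n = 4 for MesoT where MesoT-derived MLC are set against day 18 and day 22.

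**Figure D1:**
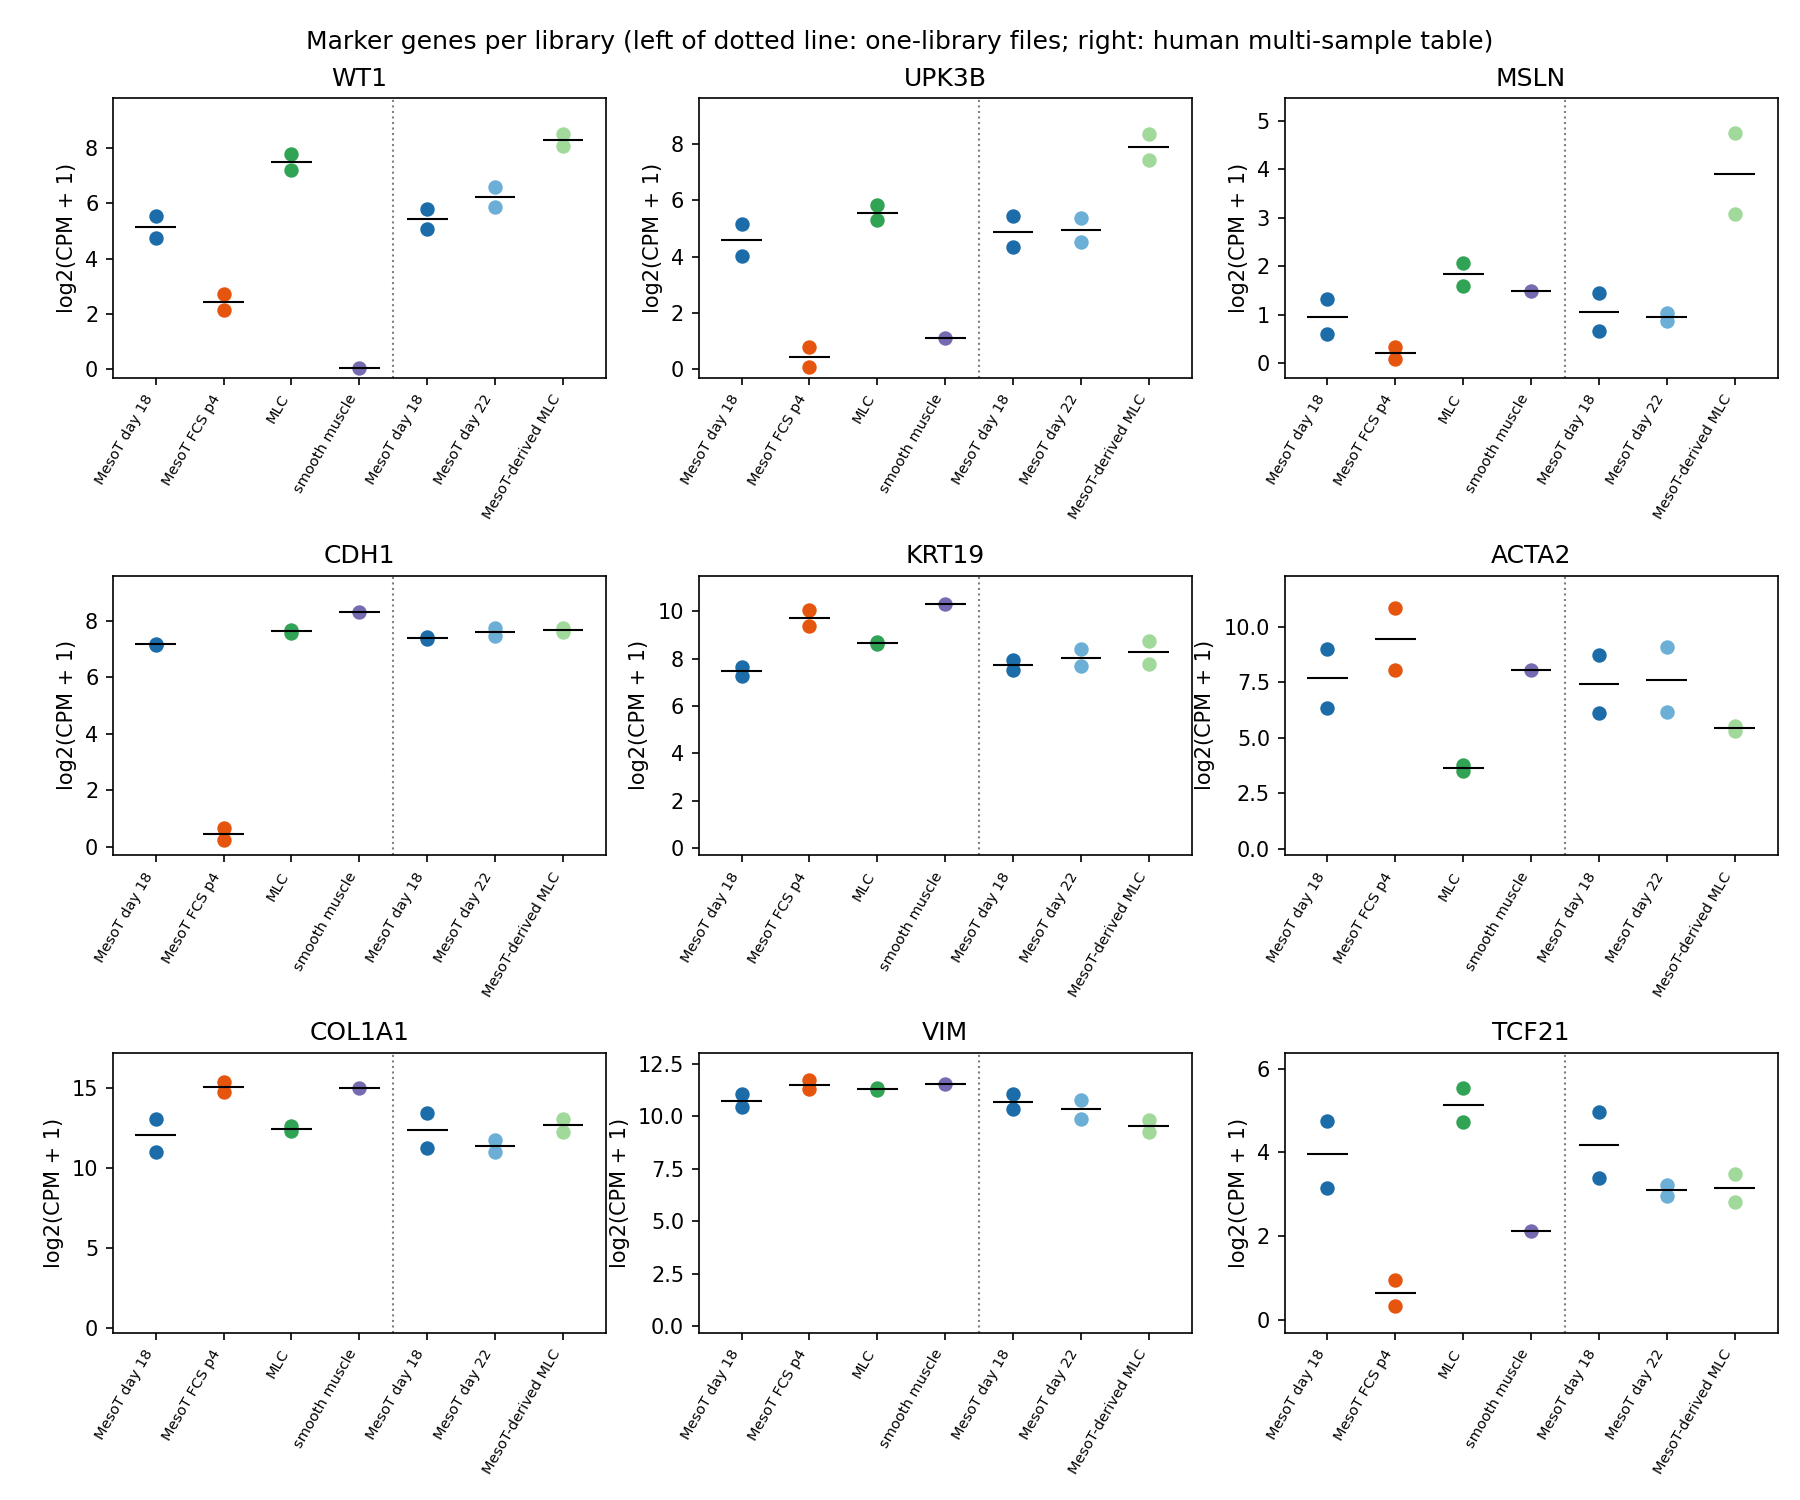
Levels of 9 marker genes in log2(CPM + 1) for each human library, with points for libraries and lines for group means; groups left of the dotted line come from the one-library files and groups right of it from the human table. CDH1 lay at 0.580 and 0.168 CPM in the MesoT FCS libraries and between 142 and 322 CPM in the other one-library files.

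The same labelled MesoT day 18 samples were counted differently in the 2 sets. Of 22110 genes compared, 12732 (57.6%) were counted alike. Among 865 named antisense genes, 711 (82.2%) were outside that tolerance. Antisense genes took 7859 and 9001 CPM at day 18 in the one-library files and 2358 and 3610 in the human table. In MLC they took 2848 and 2897. Whether counting used the strand is not stated, so reads of a gene and its antisense partner cannot be told apart and every antisense gene is uncertain.

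**Figure D2:**
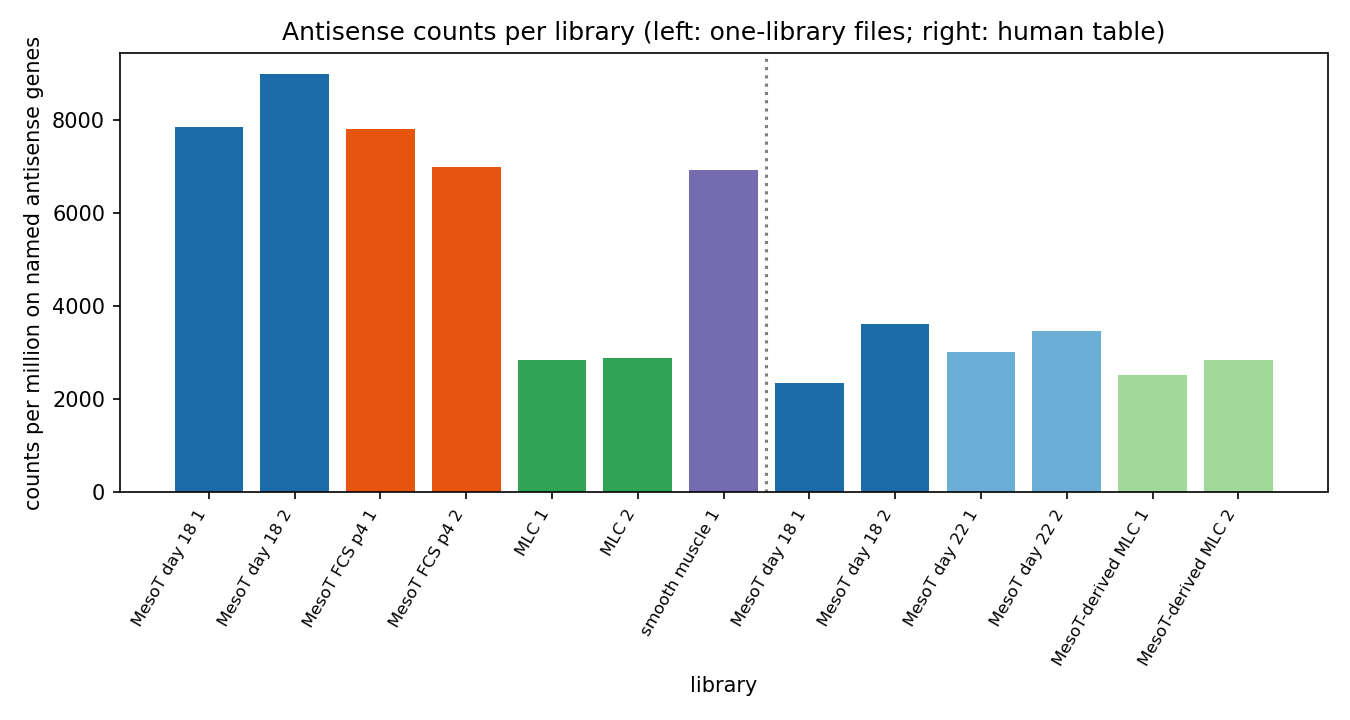
CPM on named antisense genes in each human library, one bar per library, with the one-library files left of the dotted line and the human table right of it. MLC bars reach 2848 and 2897, while the other one-library files lie between 6943 and 9001.

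Principal components asked how the groups lie relative to smooth muscle, although stratified keratin genes, given with its comparison, leave open whether the library labelled so is smooth muscle alone. In the one-library files PC1 (63.1% of variance) set MLC, at 106 and 107, against MesoT FCS, at -93.2 and -97.2, with MesoT day 18 near the centre. The library labelled smooth muscle had its highest position on PC2 (22.8%), at 71.5, beside MesoT day 18 at 46.0 and 38.2. Across the 1000 most variable genes, its mean Spearman correlation was 0.416 with MesoT day 18, 0.342 with MesoT FCS and 0.0403 with MLC, where genes are not independent replicates. Over all tested genes these were 0.895, 0.879 and 0.830. On PC3 (9.46%) the library lay at 55.7, opposite MesoT day 18 at -40.8 and -36.1. In the human table PC1 (67.5%) separated MesoT-derived MLC from MesoT, and PC2 (21.2%) separated MesoT replicate 1 (37.8 at day 18, 22.0 at day 22) from replicate 2 (-30.8 and -33.4).

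**Figure D3:**
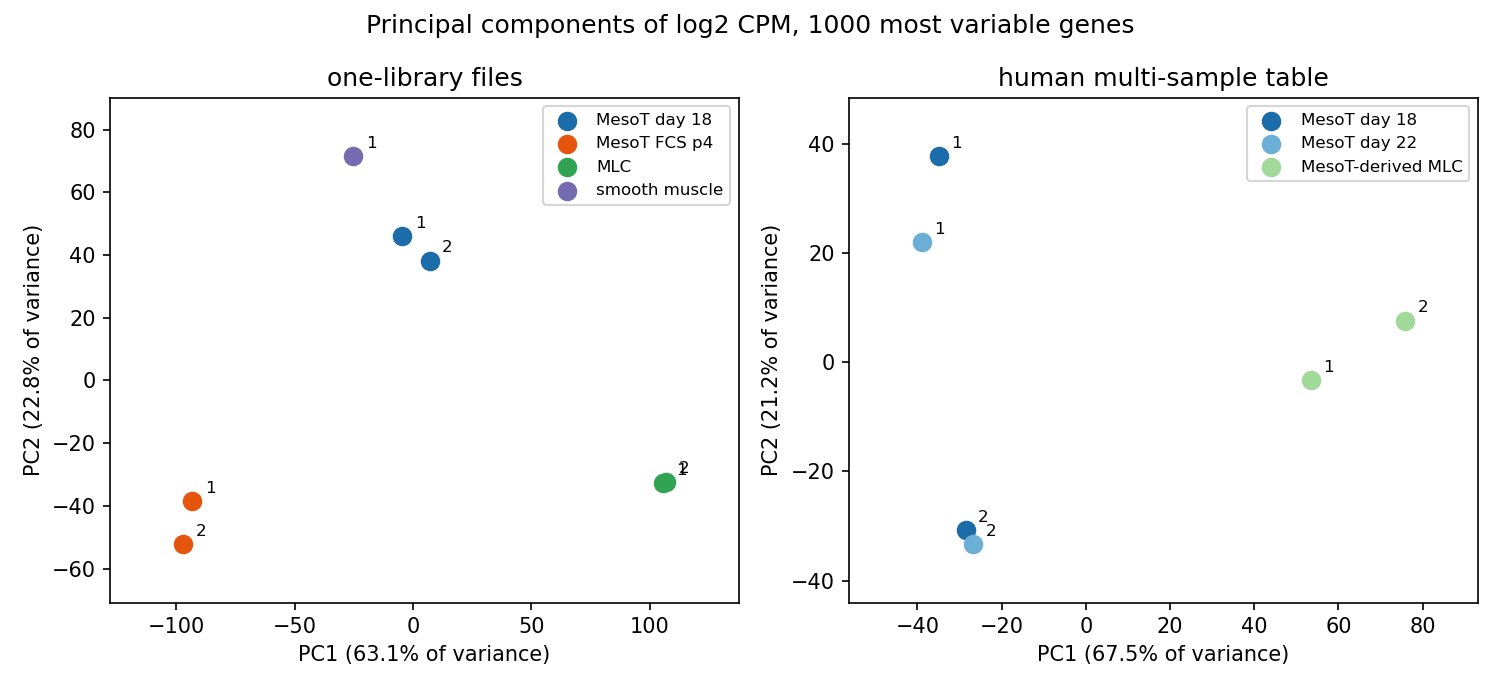
Positions of the human libraries on PC1 and PC2 of log2 CPM over the 1000 most variable genes, one point per library with its replicate number, for the one-library files (left) and the human table (right). On the left PC1 runs from -97.2 to 107.

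The first comparison asked how epithelial MLC differ from MesoT at day 18. The MLC libraries also stood apart in depth, given above, and in mitochondrial share (6.84% and 7.76% against 3.42% and 3.35%), so these differences lie along every MLC comparison within the one-library files. WT1 was higher in MLC (log2 fold change 2.34 ± 0.39, edgeR adjusted p = 0.00947, 183 ± 48.8 against 36.1 ± 14.4 CPM). So was the epithelial keratin gene KRT19 (log2 fold change 1.19 ± 0.29, edgeR adjusted p = 0.0342, 400.1 ± 16.3 against 176 ± 32.6 CPM). EZR, encoding a linker of membrane and actin, was also higher (log2 fold change 1.67 ± 0.20, edgeR adjusted p = 0.00330, 932 ± 76.1 against 293 ± 16.7 CPM). HAND1, a factor of lateral mesoderm, had a log2 fold change of 4.07 ± 0.18 (edgeR adjusted p = 0.000280, 338 ± 27.03 against 20.1 ± 0.222 CPM). The smooth muscle actin gene ACTA2 was lower (log2 fold change -4.71 ± 1.24, edgeR adjusted p = 0.0412, 11.4 ± 1.504 against 298 ± 307 CPM), although its day 18 libraries held 15983 and 2360 counts and it was not counted alike. UPK3B (0.92 ± 0.63, edgeR adjusted p = 0.331), MSLN (1.38 ± 0.71), CDH1 (0.47 ± 0.30), COL1A1 (0.07 ± 0.69), VIM (0.51 ± 0.31) and TCF21 (1.07 ± 0.68) did not pass the threshold.

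Among strongly expressed genes, the highest log2 fold changes in MLC belonged to RXRG (5.90 ± 0.24), a retinoid receptor gene, HCN4 (5.59 ± 0.55), a pacemaker channel gene, and the immediate early genes FOS (5.24 ± 1.44) and EGR1 (4.76 ± 1.24). DES (5.19 ± 1.13), encoding desmin, and CDH23 (4.77 ± 0.45), an atypical cadherin gene not counted alike, followed. FOS lost its call in 7 of 13 alternative fits, limma voom among them, and EGR1 and DES lost theirs in 5 each. The lowest were ATP6V1C2 (-6.94 ± 0.34), STARD4-AS1 (-6.49 ± 0.40), PITX1-AS1 (-6.10 ± 0.29), LRRC75A (-6.08 ± 0.32), BEST1 (-6.06 ± 0.51) and the matrix gene MGP (-6.03 ± 1.04). Of these 6, only MGP was counted alike. With the day 18 counts of the human table, the log2 fold change was -1.105 for ATP6V1C2, -0.40 for LRRC75A and 0.09 for BEST1, the last a change of sign.

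Of 20 mesothelial genes tested, 8 were higher and 1 lower (8 and 2 adjusted over the list alone). Their median was 1.13 log2 (camera adjusted p = 0.0119, and adjusted p = 0.735 with an estimated correlation), and on genes counted alike the list was not called (camera adjusted p = 0.0690). CLDN15 (1.91 ± 0.29) rose with WT1 and EZR, while ALDH1A2 (-2.73 ± 0.62), which makes retinoic acid, was the gene called lower. In the BMP response list of 16 genes, 5 were higher and 0 lower (10 and 0 adjusted over the list alone). Their median was 1.06 log2 (camera adjusted p = 0.000968, and adjusted p = 0.735 with an estimated correlation). Examples were SMAD9 (1.71 ± 0.19), SMAD6 (1.92 ± 0.46) and ID2 (1.099 ± 0.28). Cell cycle genes were higher as a group: 20 of 24 were higher and 0 lower (21 and 0 adjusted over the list alone). Their median was 1.39 log2 (camera adjusted p = 1.40e-09, and adjusted p = 0.735 with an estimated correlation). MKI67 (2.01 ± 0.31), a marker of cycling cells, went with PLK1 (1.49 ± 0.22), RRM2 (1.77 ± 0.26) and KIF20A (1.81 ± 0.30). Among 23 posterior HOX genes, 1 was higher and 10 lower (1 and 12 adjusted over the list alone). Their median was -3.15 log2 (camera adjusted p = 0.00181, and adjusted p = 0.735 with an estimated correlation). Examples were HOXB9 (-2.42 ± 0.30), HOXA7 (-2.83 ± 0.36), HOXA6 (-3.31 ± 0.49) and HOXD8 (-4.41 ± 0.70). HOXA7 was not counted alike and had -0.80 with the other day 18 counts.

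Of 14 endothelial genes tested 0 were higher and 6 lower (1 and 7 adjusted over the list alone). Their median was -3.53 log2 (camera adjusted p = 0.0304, and adjusted p = 0.735 with an estimated correlation). ERG (-8.23 ± 0.52), an endothelial factor, was at 0.0269 ± 0.0180 against 9.14 ± 0.934 CPM, and EGFL7 (-1.28 ± 0.18), ESAM (-2.99 ± 0.48) and CDH5 (-3.31 ± 0.66) were lower too. For 20 mesenchymal genes 0 were higher and 6 lower (0 and 6 adjusted over the list alone). Their median was -0.91 log2 (camera adjusted p = 0.271, and 0.0464 on genes counted alike). Examples were FAP (-3.05 ± 0.46), FOXC2 (-2.59 ± 0.41), TNC (-3.38 ± 0.64) and ZEB1 (-1.41 ± 0.29). For 18 contractile genes 1 was higher and 6 lower (2 and 8 adjusted over the list alone). Their median was -0.99 log2 (camera adjusted p = 0.271). Examples were MYH11 (-6.12 ± 0.50), MYOCD (-4.24 ± 0.73) and ACTG2 (-5.17 ± 1.02). MYH11 was not counted alike but kept its call in each of 12 alternative fits. For 11 pericyte genes 0 were higher and 4 lower (0 and 7 adjusted over the list alone). Their median was -1.73 log2 (camera adjusted p = 0.115, and 0.0204 on genes counted alike). Examples were NOTCH3 (-1.73 ± 0.27), FOXS1 (-2.53 ± 0.58), RGS5 (-2.78 ± 0.70) and KCNJ8 (-3.11 ± 0.82). For 18 TGF-beta response genes 2 were higher and 6 lower (3 and 8 adjusted over the list alone). Their median was -1.44 log2, with NOX4 (-1.29 ± 0.21), PMEPA1 (-2.47 ± 0.42) and LEFTY2 (a ratio of 0.00418 with a counting interval of 0.000502 to 0.0153) lower, COL7A1 (1.41 ± 0.22) higher (camera adjusted p = 0.553). In the junction list of 25 genes 3 were higher and 0 lower (2 and 0 adjusted over the list alone). Their median was 0.12 log2, led by PKP3 (2.13 ± 0.23) and GRHL2 (0.76 ± 0.19) (camera adjusted p = 0.271). ESRP1 (0.97 ± 0.30) did not pass.

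Hepatocyte and gut epithelium genes were higher in MLC, and those named here were low at day 18 and not counted alike. Of 13 hepatocyte genes tested, 7 were higher and 0 lower (10 and 0 adjusted over the list alone). Their median was 5.01 log2 (camera adjusted p = 0.000297, and adjusted p = 0.735 with an estimated correlation), with AFP at 59.4 ± 35.6 against 0.658 ± 0.520 CPM and SERPINA1 at least 137-fold higher. APOB (5.26 ± 0.62) and TTR (4.28 ± 0.65), for serum proteins, were higher at 11.6 ± 4.78 against 0.302 ± 0.153 CPM and 3.31 ± 0.736 against 0.168 ± 0.101 CPM. Of 11 gut epithelium genes, 6 were higher and 0 lower (7 and 0 adjusted over the list alone). Their median was 5.80 log2, or 3.96 with genes at 0 in a group set at their bound (camera adjusted p = 0.00302, and adjusted p = 0.735 with an estimated correlation), with FABP1 at least 266-fold higher, KRT20 at least 75.4-fold higher, LGALS4 (6.61 ± 0.61) and CDH17 (5.80 ± 0.93). Each list held 2 genes counted alike, too few to test on such genes alone.

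In total 5666 of 23049 genes passed, 1804 higher and 3862 lower in MLC. Among the 12726 tested genes counted alike, 2257 passed, 1325 higher (58.7%) and 932 lower, against 31.8% higher over all genes, and of 1016 antisense genes 15 were higher and 470 lower. A fit restricted to genes counted alike called 993, 397 higher and 596 lower, and moved the median log2 fold change by -0.15. The count was 1720 without MLC replicate 1 and 1714 without MLC replicate 2. Without MLC replicate 1, 35 (edgeR adjusted p from 0.0516 to 0.231) of the 59 named genes past the threshold no longer passed, WT1, KRT19, MKI67 and FOS among them. Without MLC replicate 2 this held for 33 (edgeR adjusted p from 0.05003 to 0.230), without MesoT day 18 replicate 1 for 5 (edgeR adjusted p from 0.0505 to 0.103) and without MesoT day 18 replicate 2 for 7 (edgeR adjusted p from 0.0522 to 0.131).

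The next comparison asked what changes when MesoT renew in serum. CDH1, encoding E-cadherin, was lower in MesoT FCS (log2 fold change -8.51 ± 0.45, edgeR adjusted p = 0.00163, 0.374 ± 0.292 against 143 ± 1.35 CPM), and its regulator gene GRHL2 had 0 counts there (at least 518-fold lower, 0 ± 0 against 38.7 ± 6.18 CPM). WT1 was lower (log2 fold change -2.996 ± 0.41, edgeR adjusted p = 0.00778, 4.49 ± 1.54 against 36.1 ± 14.4 CPM). So were UPK3B (log2 fold change -5.91 ± 0.86, edgeR adjusted p = 0.00876, 0.385 ± 0.466 against 24.8 ± 13.6 CPM) and TCF21 (log2 fold change -4.83 ± 0.85, edgeR adjusted p = 0.0138, 0.609 ± 0.482 against 16.9 ± 12.8 CPM). COL1A1, encoding a fibrillar collagen, was higher (log2 fold change 2.72 ± 0.73, edgeR adjusted p = 0.0407, 34797 ± 11129 against 5296 ± 4679 CPM). So was KRT19 (log2 fold change 2.28 ± 0.30, edgeR adjusted p = 0.00738, 856 ± 288 against 176 ± 32.6 CPM). VIM (0.73 ± 0.31), MSLN (-2.55 ± 0.87) and ACTA2 (1.81 ± 1.09, with 40980 and 4730 counts in the MesoT FCS libraries) did not pass.

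The highest log2 fold changes in MesoT FCS belonged to MMP1 (8.61 ± 1.03), a collagenase gene, CD44 (7.15 ± 1.21), a hyaluronan receptor gene, and NT5E (7.14 ± 0.53), a mesenchymal surface marker; MMP1 and CD44 were not counted alike. HSPB6 (6.82 ± 0.47), SCN9A (6.36 ± 1.06) and CAV1 (6.36 ± 0.35) followed. The lowest were the retinoic acid hydroxylase gene CYP26B1 (-10.70 ± 1.23), the glypican gene GPC3 (-8.51 ± 0.73), COL14A1 (-7.53 ± 0.56), CAPN6 (-7.45 ± 1.095), CRHBP (-6.31 ± 1.27) and the limb and lung factor TBX4 (-6.30 ± 1.18).

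Of 25 junction genes, 0 were higher and 20 lower (0 and 21 adjusted over the list alone). Their median was -4.51 log2 (camera adjusted p = 1.00e-09, and adjusted p = 0.164 with an estimated correlation), with ST14 at a ratio of 0.000988 with a counting interval of 2.50e-05 to 0.00551 and TJP3 at a ratio of 0.00680 with a counting interval of 0.000821 to 0.0247. Response lists of WNT, BMP and retinoic acid, each supplied in MesoT medium, were called lower. Whether the medium is the cause was not tested. For WNT response 2 of 16 were higher and 11 lower (2 and 11 adjusted over the list alone). Their median was -4.22 log2 (camera adjusted p = 0.000975, and adjusted p = 0.414 with an estimated correlation). Examples were AXIN2 (-4.32 ± 0.21), LEF1 (-7.97 ± 0.45), RNF43 (-4.12 ± 0.25) and NKD1 (-9.37 ± 0.65). For BMP response 0 of 16 were higher and 9 lower (0 and 9 adjusted over the list alone). Their median was -1.75 log2 (camera adjusted p = 0.00151, and adjusted p = 0.550 with an estimated correlation). Examples were SMAD9 (-2.10 ± 0.19), MSX2 (-4.58 ± 0.45) and ID1 (-1.78 ± 0.27), and HAND1 at a ratio of 0.00371 with a counting interval of 0.000763 to 0.0109. For retinoic acid response 1 of 18 was higher and 9 lower (1 and 10 adjusted over the list alone). Their median was -2.42 log2 (camera adjusted p = 0.00205, and adjusted p = 0.659 with an estimated correlation). Examples were RARB (-3.04 ± 0.31) and CYP26A1 at a ratio of 0.000149 with a counting interval of 3.78e-06 to 0.000831. Of 14 pluripotency genes, 0 were higher and 5 lower (0 and 8 adjusted over the list alone). Their median was -3.71 log2, or -2.46 with genes at 0 in a group set at their bound (camera adjusted p = 0.00205, and adjusted p = 0.550 with an estimated correlation), and on genes counted alike the list was not called (camera adjusted p = 0.0575). Examples were LIN28B (-3.62 ± 0.22), ZFP42 (-3.81 ± 0.62) and DPPA4 (-2.60 ± 0.58), and POU5F1, which has near-identical copies, at a ratio of 0.00514 with a counting interval of 0.000130 to 0.0289.

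Cell cycle genes rose in MesoT FCS, where 14 of 24 were higher and 0 lower (19 and 0 adjusted over the list alone). Their median was 1.27 log2 (camera adjusted p = 4.21e-09, and adjusted p = 0.604 with an estimated correlation). Examples were PLK1 (2.82 ± 0.23), AURKA (2.16 ± 0.24), RRM2 (2.19 ± 0.26) and TPX2 (2.47 ± 0.30). For targets of SRF and YAP, factors that respond to cell tension, 7 of 20 were higher and 0 lower (12 and 0 adjusted over the list alone). Their median was 1.87 log2 (camera adjusted p = 0.000156, and adjusted p = 0.634 with an estimated correlation). Examples were AXL (3.37 ± 0.20), ACTG1 (1.88 ± 0.29) and FLNA (2.48 ± 0.45). In the contractile list 5 of 18 were higher and 1 lower (7 and 1 adjusted over the list alone). Their median was 1.84 log2 (camera adjusted p = 0.00929, and adjusted p = 0.773 with an estimated correlation). Of these, MYLK (3.61 ± 0.51), ACTG2 (5.69 ± 0.999) and TPM1 (1.86 ± 0.39) were higher and ITGA8 (-5.75 ± 0.52) lower. Of 20 mesenchymal genes 1 was higher and 0 lower (1 and 0 adjusted over the list alone). Their median was 0.88 log2 (camera adjusted p = 0.00959, and adjusted p = 0.550 with an estimated correlation). ITGA5 (2.36 ± 0.46) passed, while FBN1 (1.53 ± 0.46), FOXC2 (1.31 ± 0.39) and FN1 (1.90 ± 0.66) did not. FBN1 passed in 7, FOXC2 in 5 and FN1 in 4 of 13 alternative fits. On genes counted alike the contractile and mesenchymal lists were not called (camera adjusted p = 0.0551 and 0.0782). Matrix genes went both ways: 5 of 20 were higher and 3 lower (6 and 3 adjusted over the list alone). Their median was 0.88 log2 (camera adjusted p = 0.0551). Of these, BGN (3.53 ± 0.42) and THBS2 (4.72 ± 1.03) were higher and DCN (-2.34 ± 0.25) and LUM (-2.19 ± 0.37) lower. Of 20 mesothelial genes 1 was higher and 6 lower (1 and 8 adjusted over the list alone). Their median was -1.60 log2, or -1.05 with genes at 0 in a group set at their bound (camera adjusted p = 0.0551), with ALDH1A2 at -7.35 ± 0.83.

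In this comparison 6301 of 23049 genes passed, against 3253 with only these groups fitted. Of the 6301, 2991 were higher and 3310 lower in MesoT FCS, while limma voom called 3224 higher and 3068 lower. The count was 2783 without MesoT FCS replicate 1 and 2985 without MesoT FCS replicate 2. Without MesoT FCS replicate 1, 9 (edgeR adjusted p from 0.0508 to 0.114) of the 52 named genes past the threshold no longer passed, COL1A1, TCF21, ITGA5 and FLNA among them. Without replicate 2 of MesoT FCS this held for 5 (edgeR adjusted p from 0.0502 to 0.130), and without MesoT day 18 replicate 2 for TPM1 alone (edgeR adjusted p = 0.0556).

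MLC were then compared with MesoT FCS, the epithelial form against the serum-renewed mesenchymal form. CDH1 was higher in MLC (log2 fold change 8.98 ± 0.46, edgeR adjusted p = 0.000197, 198 ± 9.87 against 0.374 ± 0.292 CPM). So were WT1 (log2 fold change 5.34 ± 0.45, edgeR adjusted p = 0.000628, 183 ± 48.8 against 4.49 ± 1.54 CPM) and UPK3B (log2 fold change 6.84 ± 0.88, edgeR adjusted p = 0.00218, 47.0 ± 12.52 against 0.385 ± 0.466 CPM). MSLN (log2 fold change 3.93 ± 0.87, edgeR adjusted p = 0.0131, 2.62 ± 0.831 against 0.162 ± 0.14996 CPM) and TCF21 (log2 fold change 5.90 ± 0.88, edgeR adjusted p = 0.00356, 35.4 ± 14.01 against 0.609 ± 0.482 CPM) were higher too. COL1A1 (log2 fold change -2.64 ± 0.73, edgeR adjusted p = 0.0277, 5574 ± 761 against 34797 ± 11129 CPM), KRT19 (log2 fold change -1.097 ± 0.29, edgeR adjusted p = 0.0246, 400.1 ± 16.3 against 856 ± 288 CPM) and ACTA2 (log2 fold change -6.52 ± 1.35, edgeR adjusted p = 0.0107, 11.4 ± 1.504 against 1047 ± 1107 CPM) were lower, and VIM (-0.22 ± 0.31, edgeR adjusted p = 0.576) did not pass.

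The highest log2 fold changes in MLC were those of the basement membrane gene FREM2 (12.75 ± 0.78), the cartilage collagen gene COL2A1 (9.60 ± 0.48), IGDCC3 (9.21 ± 0.82), CYP26B1 (8.76 ± 1.15) and GPC3 (7.95 ± 0.71), beside CDH1. The lowest were the contractile actin gene ACTG2 (-10.85 ± 1.26), the BMP antagonist gene GREM1 (-9.31 ± 0.41), CLMAT3 (-8.77 ± 0.82), a non-coding gene not counted alike, THBS2 (-8.70 ± 1.24), ITGA11 (-8.23 ± 1.104) and CPA4 (-8.17 ± 0.58). Of 25 junction genes, 22 were higher and 0 lower (22 and 0 adjusted over the list alone). Their median was 4.37 log2 (camera adjusted p = 3.43e-09, and adjusted p = 0.177 with an estimated correlation), with GRHL2 at least 881-fold higher and ESRP1, a splicing factor gene of epithelia, at a ratio of 1294 with a counting interval of 358 to 10689. ST14 had a ratio of 706 with a counting interval of 127 to 27884. Of 20 mesothelial genes, 13 were higher and 1 lower (15 and 1 adjusted over the list alone). Their median was 3.28 log2 (camera adjusted p = 0.00132, and adjusted p = 0.447 with an estimated correlation). Examples were CLDN15 (2.43 ± 0.29) and EZR (1.45 ± 0.20).

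BMP response genes were higher in MLC, where 13 of 16 were higher and 0 lower (13 and 0 adjusted over the list alone). Their median was 2.59 log2 (camera adjusted p = 1.66e-05, and adjusted p = 0.383 with an estimated correlation). Examples were SMAD9 (3.81 ± 0.21), MSX2 (5.52 ± 0.47) and ID1 (2.53 ± 0.27), and HAND1 at a ratio of 4537 with a counting interval of 1553 to 22003. For WNT response 12 of 16 were higher and 3 lower (12 and 3 adjusted over the list alone). Their median was 4.58 log2, or 4.08 with genes at 0 in a group set at their bound (camera adjusted p = 0.00449, and adjusted p = 0.383 with an estimated correlation). Examples were AXIN2 (4.59 ± 0.21), RNF43 (5.70 ± 0.27), LEF1 (8.05 ± 0.45) and NKD1 (8.37 ± 0.64). For retinoic acid response 8 of 18 were higher and 1 lower (9 and 1 adjusted over the list alone). Their median was 1.72 log2 (camera adjusted p = 0.00526, and adjusted p = 0.662 with an estimated correlation). Examples were RARB (2.14 ± 0.30) and CYP26A1 at a ratio of 2044 with a counting interval of 367 to 80759. Of 20 mesenchymal genes 2 were higher and 11 lower (2 and 11 adjusted over the list alone). Their median was -2.01 log2 (camera adjusted p = 0.0172, and adjusted p = 0.561 with an estimated correlation). Examples were FOXC2 (-3.90 ± 0.43), FAP (-3.28 ± 0.47), ITGA5 (-3.38 ± 0.48) and TNC (-4.65 ± 0.68). Of 18 contractile genes 1 was higher and 14 lower (1 and 15 adjusted over the list alone). Their median was -3.09 log2 (camera adjusted p = 0.00894, and adjusted p = 0.673 with an estimated correlation). Of these, MYH11 (-5.79 ± 0.49) and MYOCD (-5.14 ± 0.76) were lower and ITGA8 (6.24 ± 0.53) higher. Of 11 pericyte genes 0 were higher and 5 lower (0 and 5 adjusted over the list alone). Their median was -2.22 log2 (camera adjusted p = 0.0172, and adjusted p = 0.662 with an estimated correlation). Examples were MCAM (-3.89 ± 0.47), CD248 (-3.60 ± 0.48), CSPG4 (-3.44 ± 0.57) and PDGFRB (-2.22 ± 0.40).

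For this pair 11272 of 23049 genes passed, 5202 higher (46.1%) and 6070 lower in MLC, and among 6235 such genes counted alike 3527 were higher (56.6%). A fit restricted to genes counted alike called 6133, 3064 higher and 3069 lower, and moved the median by -0.10 log2. The count was 5558 without MLC replicate 1 and 4962 without MLC replicate 2. Without MLC replicate 1, ACTA2, COL1A1, KRT19, MSLN and PDGFRB no longer passed, with edgeR adjusted p from 0.0553 to 0.1505. Without MLC replicate 2, ACTA2, COL1A1 and KRT19 no longer passed (0.0794 to 0.133). COL1A1 also failed without MesoT FCS replicate 1, with KRT19 (0.0559 and 0.102), and without MesoT FCS replicate 2, with MSLN (0.0544 and 0.0973).

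Replated MesoT were compared with MesoT to ask whether MesoT can take the epithelial form. The replated cells also had the TGF-beta receptor inhibitor, with no WNT3A or BMP4 listed. Replating and medium therefore cannot be told apart here. MSLN was higher in MesoT-derived MLC (log2 fold change 3.99 ± 0.60, edgeR adjusted p = 0.0217, 16.6 ± 12.9 against 1.05 ± 0.487 CPM). So was UPK3B (log2 fold change 3.01 ± 0.42, edgeR adjusted p = 0.0204, 249.9 ± 107 against 31.1 ± 12.03 CPM). WT1 (log2 fold change 2.46 ± 0.30, edgeR adjusted p = 0.0162, 315 ± 64.1 against 59.6 ± 25.7 CPM) and the mesothelial gene LRRN4 (log2 fold change 3.30 ± 0.32, edgeR adjusted p = 0.0122, 912 ± 338 against 95.7 ± 33.5 CPM) were higher as well. ID3, a direct target of BMP signals, was lower (log2 fold change -3.18 ± 0.29, edgeR adjusted p = 0.0118, 42.9 ± 0.0794 against 389 ± 94.1 CPM). So was BAMBI, a pseudoreceptor gene (log2 fold change -3.47 ± 0.40, edgeR adjusted p = 0.0145, 38.0 ± 5.76 against 429.9 ± 183 CPM). CDH1 (0.16 ± 0.17, edgeR adjusted p = 0.550), KRT19 (0.43 ± 0.35), ACTA2 (-2.71 ± 1.08), COL1A1 (0.67 ± 0.63), VIM (-0.996 ± 0.39) and TCF21 (-0.60 ± 0.50) did not pass.

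The highest log2 fold changes were those of RIPOR3 (5.68 ± 0.31), which was not counted alike, the neuronal surface gene SLITRK2 (5.22 ± 0.52), COL8A2 (4.53 ± 0.51), ADAM33 (4.42 ± 0.48), the imprinted gene DIRAS3 (4.41 ± 0.53) and the prostaglandin synthase gene PTGS1 (4.34 ± 0.65). The lowest were CRHBP (-8.04 ± 1.11), the matrix gene TNC (-6.41 ± 0.98), CYP24A1 (-5.99 ± 1.18), which degrades vitamin D, LIX1 (-5.30 ± 1.03), TCIM (-5.13 ± 0.74) and the WNT agonist gene RSPO2 (-4.96 ± 0.58). Of 20 mesothelial genes, 8 were higher and 0 lower (12 and 0 adjusted over the list alone). Their median was 1.30 log2 (camera adjusted p = 3.46e-05, and adjusted p = 0.744 with an estimated correlation), PDPN (1.95 ± 0.23) among them. Of 16 BMP response genes 0 were higher and 5 lower (0 and 6 adjusted over the list alone). Their median was -1.17 log2 (camera adjusted p = 8.00e-05, and adjusted p = 0.744 with an estimated correlation). Examples were SMAD9 (-1.92 ± 0.26) and SMAD7 (-1.94 ± 0.41). Of 24 cell cycle genes 6 were higher and 0 lower (18 and 0 adjusted over the list alone). Their median was 0.92 log2 (camera adjusted p = 7.97e-07, and adjusted p = 0.744 with an estimated correlation). Examples were E2F1 (1.98 ± 0.33), MCM4 (1.23 ± 0.21), TPX2 (1.44 ± 0.27) and RRM2 (1.38 ± 0.25). Of 20 cholesterol synthesis genes 2 were higher and 0 lower (9 and 0 adjusted over the list alone). Their median was 0.66 log2 (camera adjusted p = 0.000268, and adjusted p = 0.744 with an estimated correlation); LSS (1.51 ± 0.37) and DHCR7 (1.33 ± 0.34) did not pass.

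For mesenchymal genes in MesoT-derived MLC 0 of 20 were higher and 4 lower (0 and 6 adjusted over the list alone). Their median was -0.76 log2 (camera adjusted p = 0.00544, and adjusted p = 0.744 with an estimated correlation). Examples were FOXC2 (-4.10 ± 0.47), ZEB2 (-2.02 ± 0.44) and FN1 (-3.71 ± 0.81). For TGF-beta response 2 of 18 were higher and 4 lower (2 and 4 adjusted over the list alone). Their median was -1.58 log2 (camera adjusted p = 0.0357, and adjusted p = 0.744 with an estimated correlation). Of these, NOX4 (-2.59 ± 0.23), SKIL (-2.23 ± 0.40) and LEFTY2 (-5.27 ± 1.04) were lower and COL7A1 (1.21 ± 0.21) higher. For posterior HOX genes 1 of 23 was higher and 4 lower (1 and 7 adjusted over the list alone). Their median was -1.49 log2 (camera adjusted p = 0.00632, and adjusted p = 0.744 with an estimated correlation). Of these, HOXD10 (-6.69 ± 0.67), HOXB7 (-2.06 ± 0.27) and HOXD11 (-5.47 ± 0.81) were lower and HOXD8 (1.95 ± 0.25) higher. Of 8 neural genes 0 were higher and 2 lower (0 and 3 adjusted over the list alone). Their median was -2.48 log2, or -1.95 with genes at 0 in a group set at their bound (camera adjusted p = 0.00899, and adjusted p = 0.744 with an estimated correlation); MAP2 (-4.10 ± 0.32) and STMN2 (-4.94 ± 0.78) passed, while S100B (at least 5.75-fold lower, with edgeR adjusted p = 0.140) did not pass. Of 25 junction genes 1 was higher and 0 lower (2 and 2 adjusted over the list alone). Their median was -0.51 log2 (camera adjusted p = 0.290); PKP2 (1.08 ± 0.17) passed, while EPCAM (-1.43 ± 0.33) and MARVELD2 (-0.78 ± 0.19) did not. Hepatocyte genes moved as in MLC, since 7 of 10 were higher and 0 lower (8 and 0 adjusted over the list alone). Their median was 5.92 log2 (camera adjusted p = 3.46e-05, and adjusted p = 0.744 with an estimated correlation), with the factor gene HNF4A at 10.7 ± 3.42 against 0.0709 ± 0.0262 CPM and AFP at 65.8 ± 14.1 against 0.925 ± 0.561 CPM. SERPINA1 (9.57 ± 0.94) and APOA2 (7.02 ± 0.92) were higher too. Of 11 gut epithelium genes 8 were higher and 0 lower (9 and 0 adjusted over the list alone). Their median was 3.99 log2 (camera adjusted p = 3.46e-05, and adjusted p = 0.744 with an estimated correlation). Examples were FABP2 (6.32 ± 0.55), LGALS4 (5.57 ± 0.53) and KRT20 (6.43 ± 0.89).

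In this comparison 2219 of 22316 genes passed, 1479 higher and 740 lower in MesoT-derived MLC. The fit treated the pooled MesoT libraries of day 18 and day 22 as independent. Deviations of their same-numbered libraries correlated at 0.557, so the errors here may be too small. By edgeR no gene passed, a count of 0, without MesoT day 22 replicate 1 or without MesoT-derived MLC replicate 2, so all 46 named genes past the threshold failed there, with adjusted p from 0.0562 to 0.105 and from 0.0615 to 0.253. The log2 fold changes of these genes were a median of 0.967 times those with all libraries in the first fit (from 0.881 to 1.06) and 0.907 times in the second (from 0.712 to 1.74), with the same sign. A fit with 1 library fewer also has fewer residual degrees of freedom, so a lost call does not show that the change rests on that library. The count was 182 without MesoT day 22 replicate 2, where 27 (edgeR adjusted p from 0.0509 to 0.0899) of them failed, and 309 without MesoT-derived MLC replicate 1, where 25 (edgeR adjusted p from 0.0501 to 0.172) failed. ZEB2 failed without MesoT day 18 replicate 1 (edgeR adjusted p = 0.0588) and without MesoT day 18 replicate 2 (0.0669). Against day 18 alone 380 genes passed, against day 22 alone 612, and in a fit restricted to genes counted alike 1092, with the median moved by -0.11 log2.

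The human table also allowed MesoT day 22 to be set against day 18, for time in culture. By edgeR 0 of 22316 genes passed, with 171 at an unadjusted p under 0.05 (80 higher and 91 lower), and 0 passed by DESeq2 and by limma voom. MesoT replicates 1 and 2 differed in the same genes at both days, which widens the spread used here, so 0 calls do not show that the days are alike. WT1 lay at 75.6 ± 26.5 against 43.6 ± 15.8 CPM at day 22 against day 18 (log2 fold change 0.80 ± 0.36), COL1A1 at 2681 ± 990.4 against 6741 ± 6141 CPM (-1.33 ± 0.76) and TCF21 at 7.56 ± 1.09 against 19.8 ± 14.6 CPM (-1.39 ± 0.57). UPK3B (0.01 ± 0.51), MSLN (-0.30 ± 0.75), CDH1 (0.22 ± 0.20), KRT19 (0.36 ± 0.41), ACTA2 (0.28 ± 1.08) and VIM (-0.35 ± 0.43) did not pass either. Of 20 interferon response genes 0 passed, also adjusted over the list alone. Their median was 0.71 log2, and the list moved against other genes (camera adjusted p = 1.46e-13, and adjusted p = 0.936 with an estimated correlation). Examples were OAS3 (1.102 ± 0.39), OAS2 (2.35 ± 0.82), MX1 (1.31 ± 0.59) and IFIT3 (0.71 ± 0.35). Of 24 cell cycle genes 0 passed, also adjusted over the list alone. Their median was 0.39 log2 (camera adjusted p = 1.84e-08, and adjusted p = 0.936 with an estimated correlation). Examples were KIF20A (0.67 ± 0.33), CENPF (0.52 ± 0.28), TOP2A (0.64 ± 0.35) and BUB1 (0.44 ± 0.24). Matrix genes had a median of -0.42 with 0 of 20 past the threshold and 0 adjusted over the list alone (camera adjusted p = 0.00820, and adjusted p = 0.936 with an estimated correlation). Examples were COL6A3 (-1.12 ± 0.53), COL6A1 (-0.65 ± 0.32) and COL6A2 (-0.71 ± 0.39). Basement membrane genes had a median of -0.24 with 0 of 20 past it and 0 adjusted over the list alone (camera adjusted p = 0.0367, and adjusted p = 0.936 with an estimated correlation), a call lost on genes counted alike (camera adjusted p = 0.0608). Examples were NID2 (-0.78 ± 0.30), NPNT (-0.73 ± 0.38), LAMC1 (-0.37 ± 0.22) and COL18A1 (-0.69 ± 0.48).

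The single library labelled smooth muscle was set against MesoT day 18. Its spread was taken from the other groups, so the edgeR calls and camera p-values describe this library and not the cell type. Stratified keratin genes, picked after their values were seen, leave open whether it is smooth muscle alone: KRT5 lay at 870.3 against 0.154 CPM and KRT14 at 259 against 0.0825 CPM. Contractile genes were expressed as well, with TPM1 at 1701 CPM and TAGLN, a gene outside the naming rule, at 600.2. The contractile list, given below, was not called higher than in MesoT day 18. WT1 held 1 count in this library, a ratio of 0.00114 with a counting interval of 2.88e-05 to 0.00635 (edgeR adjusted p = 0.0136, 0.0407 against 36.1 ± 14.4 CPM). KRT19 was higher (log2 fold change 2.85 ± 0.34, edgeR adjusted p = 0.0167, 1265 against 176 ± 32.6 CPM). The hemidesmosome gene COL17A1 (log2 fold change 8.13 ± 0.65, edgeR adjusted p = 0.0104, 544 against 1.93 ± 1.47 CPM) and the stratified keratin gene KRT17 (log2 fold change 6.48 ± 0.60, edgeR adjusted p = 0.0126, 319.5 against 3.58 ± 2.50 CPM) were higher too. CYP26B1 was lower (log2 fold change -6.24 ± 1.36, edgeR adjusted p = 0.0472, 14.7 against 1114 ± 623 CPM). UPK3B (-4.44 ± 1.03, edgeR adjusted p = 0.0532), CDH1 (1.17 ± 0.36), COL1A1 (2.63 ± 0.81), ACTA2 (-0.15 ± 1.31), VIM (0.76 ± 0.37), MSLN (0.83 ± 0.85) and TCF21 (-2.34 ± 0.94) did not pass.

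Besides COL17A1 and KRT17, the highest log2 fold changes were those of the epithelial gene SFN (7.44 ± 0.84), the anchoring collagen gene COL7A1 (6.53 ± 0.28), LAMB3 (6.37 ± 0.49), for a laminin chain of epithelia, and the cardiac actin gene ACTC1 (5.82 ± 0.59). Lowest beside CYP26B1 were HOXA3, with a ratio of 0.000798 with a counting interval of 9.67e-05 to 0.00289, PDE11A, not counted alike, with a ratio of 0.00131 with a counting interval of 0.000159 to 0.00474, the glutamate receptor gene GRIA4 (-7.32 ± 0.49), the complement gene CFI (-7.31 ± 1.58) and TMEM132C (-6.55 ± 1.27). Of 18 contractile genes 0 were higher and 1 lower (2 and 1 adjusted over the list alone). Their median was 0.33 log2 (camera adjusted p = 0.223); ITGA8 (-4.10 ± 0.62) was the gene called, and MYLK (2.201 ± 0.54), SMTN (2.25 ± 0.57) and TPM1 (1.35 ± 0.44) did not pass. MYLK passed in 4 and SMTN in 3 of 8 alternative fits, and with 1 library the fit recovered 0% of 2-fold and 64% of 8-fold simulated changes. Of 25 junction genes 9 were higher and 0 lower (14 and 0 adjusted over the list alone). Their median was 1.47 log2 (camera adjusted p = 4.77e-08, and adjusted p = 0.214 with an estimated correlation). Examples were CLDN4 (2.92 ± 0.30), PKP3 (2.56 ± 0.26) and TJP3 (2.22 ± 0.28). Of 20 matrix genes 4 were higher and 1 lower (10 and 1 adjusted over the list alone). Their median was 1.28 log2 (camera adjusted p = 0.00669, and adjusted p = 0.699 with an estimated correlation). Of these, BGN (3.59 ± 0.46), COL6A1 (1.98 ± 0.39) and MFAP5 (6.89 ± 1.39) were higher and DCN (-1.95 ± 0.32) lower. Among 15 NOTCH pathway genes 5 were higher and 0 lower (11 and 1 adjusted over the list alone). Their median was 1.88 log2 (camera adjusted p = 0.000100, and adjusted p = 0.699 with an estimated correlation). Examples were JAG1 (1.70 ± 0.25), NOTCH3 (1.87 ± 0.30), LFNG (2.55 ± 0.53) and HEY1 (2.65 ± 0.59).

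Anterior HOX genes were lower in this library, where 0 of 14 were higher and 8 lower (0 and 13 adjusted over the list alone). Their median was -7.98 log2, or -4.74 with genes at 0 in a group set at their bound (camera adjusted p = 1.27e-06, and adjusted p = 0.699 with an estimated correlation). Examples were HOXB5 (-2.31 ± 0.34) and HOXA2 at a ratio of 0.00207 with a counting interval of 5.23e-05 to 0.0115. Retinoic acid response genes share several of these members, and 0 of 18 were higher and 7 lower (1 and 13 adjusted over the list alone). Their median was -3.21 log2, or -2.69 with genes at 0 in a group set at their bound (camera adjusted p = 5.71e-05, and adjusted p = 0.699 with an estimated correlation), with NRIP1 (-2.25 ± 0.29) and HOXA5 at a ratio of 0.00131 with a counting interval of 0.000158 to 0.00472. For TGF-beta response 2 of 18 were higher and 0 lower (3 and 0 adjusted over the list alone). Their median was 0.75 log2 (camera adjusted p = 0.0113, and adjusted p = 0.717 with an estimated correlation). TGFBI (3.17 ± 0.63) passed, while TGFB1 (2.31 ± 0.55) and ID1 (0.90 ± 0.31) did not. TGFBI lost its call in 3 of 8 alternative fits, while TGFB1 passed in 5 of 7 and ID1 in 1 of 8. Of 20 mesothelial genes 4 were higher and 2 lower (4 and 7 adjusted over the list alone). Their median was 0.16 log2, whereas their mean was -1.35 and camera pointed down (adjusted p = 0.782). UPK1B (6.96 ± 1.04), not counted alike, and CALB2 (2.10 ± 0.37) were higher. In this comparison 1998 of 23049 genes passed, 1172 higher (58.7%) and 826 lower, a split that was 68.8% higher by limma voom and 48.8% by DESeq2 (2403 higher and 2522 lower), so the majority direction depends on the method. Without MesoT day 18 replicate 1 the count was 4292, and 3 (edgeR adjusted p from 0.0540 to 0.0765) of the 33 named genes past the threshold, HEY1, MFAP5 and TGFBI, failed. Without MesoT day 18 replicate 2, CFI, COL6A1, LFNG, MFAP5 and TGFBI failed (edgeR adjusted p from 0.0607 to 0.0863).

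The MLC routes were compared directly across the sets of files, so any difference in counting or sequencing lies along the route. UPK3B was lower in MLC than in MesoT-derived MLC (log2 fold change -2.01 ± 0.60, edgeR adjusted p = 0.0275, 51.7 ± 13.6 against 209 ± 92.1 CPM). So was MSLN (log2 fold change -2.27 ± 0.73, edgeR adjusted p = 0.0367, 2.88 ± 0.905 against 13.9 ± 10.96 CPM). VIM (log2 fold change 2.13 ± 0.38, edgeR adjusted p = 0.00353, 2758 ± 184 against 631 ± 166 CPM) and TCF21 (log2 fold change 2.53 ± 0.65, edgeR adjusted p = 0.0150, 39.0 ± 15.53 against 6.73 ± 2.35 CPM) were higher in MLC. WT1 (-0.38 ± 0.38, edgeR adjusted p = 0.447), CDH1 (0.36 ± 0.27), KRT19 (0.72 ± 0.38), ACTA2 (-1.49 ± 1.17) and COL1A1 (0.13 ± 0.65) did not pass. Of 16 BMP response genes 12 were higher and 0 lower (14 and 0 adjusted over the list alone). Their median was 2.72 log2 (camera adjusted p = 1.25e-06, and adjusted p = 0.327 with an estimated correlation). Examples were SMAD9 (3.44 ± 0.27), ID3 (3.30 ± 0.27), HAND1 (5.38 ± 0.59) and MSX2 (2.79 ± 0.39). Of 20 lateral plate factors 9 were higher and 2 lower (9 and 2 adjusted over the list alone). Their median was 0.59 log2 (camera adjusted p = 0.0321, and adjusted p = 0.508 with an estimated correlation). This call was lost on genes counted alike (camera adjusted p = 0.210) and through MesoT day 18 in each set (0.0606). Examples were TBX5 (2.83 ± 0.34), FOXF2 (3.85 ± 0.49) and HAND2 (1.69 ± 0.27). Of 24 cell cycle genes 5 were higher and 0 lower (3 and 0 adjusted over the list alone). Their median was 0.39 log2 (camera adjusted p = 0.0321, and adjusted p = 0.985 with an estimated correlation). This call was lost too (camera adjusted p = 0.220 and 0.109). Examples were TYMS (1.35 ± 0.23), MKI67 (1.18 ± 0.27), CENPF (0.98 ± 0.27) and CDK1 (0.99 ± 0.30). Of 20 mesothelial genes 5 were higher and 7 lower (5 and 7 adjusted over the list alone). Their median was -0.25 log2 (camera adjusted p = 0.959). Among the lower were ALDH1A2 (-5.58 ± 0.86), LRRN4 (-2.39 ± 0.59) and UPK1B (-2.32 ± 0.58).

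The highest log2 fold changes were those of SAMD11 (7.01 ± 0.67), LINC02593 (6.92 ± 0.69), the GABA receptor gene GABRP (6.79 ± 0.73), the netrin receptor gene UNC5C (6.30 ± 1.22), B3GALT5 (6.05 ± 0.25) and CCDC3 (5.92 ± 0.44). SAMD11, LINC02593 and B3GALT5 were not counted alike. The lowest were PIK3R2 (-9.08 ± 0.53), the matrix proteoglycan gene SPOCK2 (-7.16 ± 0.95), NBPF20 (-5.74 ± 0.31), which has near-identical copies, DPYSL5 (-5.69 ± 0.39), SLITRK2 (-5.62 ± 0.74) and the protease gene HTRA1 (-5.61 ± 0.85). PIK3R2, NBPF20 and DPYSL5 were not counted alike. Taken through MesoT day 18 in each set, the difference was 0.16 for PIK3R2, 1.39 for NBPF20 and 3.41 for UPK1B, each a change of sign. There UPK3B, MSLN, VIM, TCF21, LRRN4, HAND2, TYMS, MKI67, CENPF and CDK1 kept their direction and lost their calls (edgeR adjusted p from 0.0553 to 0.254). Of 24781 genes 10335 passed, 4051 higher (39.2%) and 6284 lower in MLC, and among those counted alike 2501 higher (64.6%) and 1371 lower. Relative log expression scaling moved the median by -0.11 log2 and a fit restricted to genes counted alike by -0.18. That fit called 2592, 1143 higher (44.1%) and 1449 lower, so the majority direction among genes counted alike depends on the fit. The count was 6526 without MesoT-derived MLC replicate 2, 6419 without MLC replicate 1 and 6237 without MLC replicate 2. In the last, 7 (edgeR adjusted p from 0.0787 to 0.190) of the 30 named genes past the threshold failed, UPK3B, MSLN and TCF21 among them, against 8 (edgeR adjusted p from 0.0672 to 0.313) without MesoT-derived MLC replicate 2. Of these named genes, 6 (edgeR adjusted p from 0.0616 to 0.105) failed without MLC replicate 1, and without MesoT-derived MLC replicate 1 only CDK1 and CENPF (0.0555 and 0.0789).

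Whether the same genes separate MLC and MesoT-derived MLC from MesoT was asked by comparing the fold changes of both routes. WT1 (2.34 ± 0.39 in MLC, 2.46 ± 0.30 in MesoT-derived MLC) and COL7A1 (1.41 ± 0.22, 1.21 ± 0.21) were higher in both routes. FOXC2 (-2.59 ± 0.41, -4.10 ± 0.47) and NOX4 (-1.29 ± 0.21, -2.59 ± 0.23) were lower in both. Of 18980 shared genes, 425 were called higher in both. Independent lists of these sizes would share 123. In both routes 245 were called lower, against 76.5 for independent lists, and 91 were called in opposite directions. Across genes, which are not independent replicates, Pearson's r was 0.371 and Spearman's rho 0.329. Groups without effects were simulated against the shared MesoT day 18 libraries 10 times, with 17945 genes on average past the low-count filter. They gave a mean r of 0.303, where the observed r over the same genes was 0.361. They also gave 0 shared calls, but groups without effects yield few calls, so this count decides nothing about the shared calls observed. Unlike these data, the simulations drew day 22 independently of day 18 and used the same day 18 counts in both sets. The r of groups without effects may therefore differ from the simulated one. The observed covariance over those genes was 0.688, against 0.0859 in the simulations, a difference of 0.602. With day 18 replicate 1 as the only control of MLC and replicate 2 as that of MesoT-derived MLC, r was 0.159 and no gene was called for MesoT-derived MLC by edgeR. The controls cannot be split with 2 libraries on each side, so part of the excess may come from the shared controls. Against MesoT day 22 alone, r was 0.349 and 153 genes were higher in both.

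**Figure D4:**
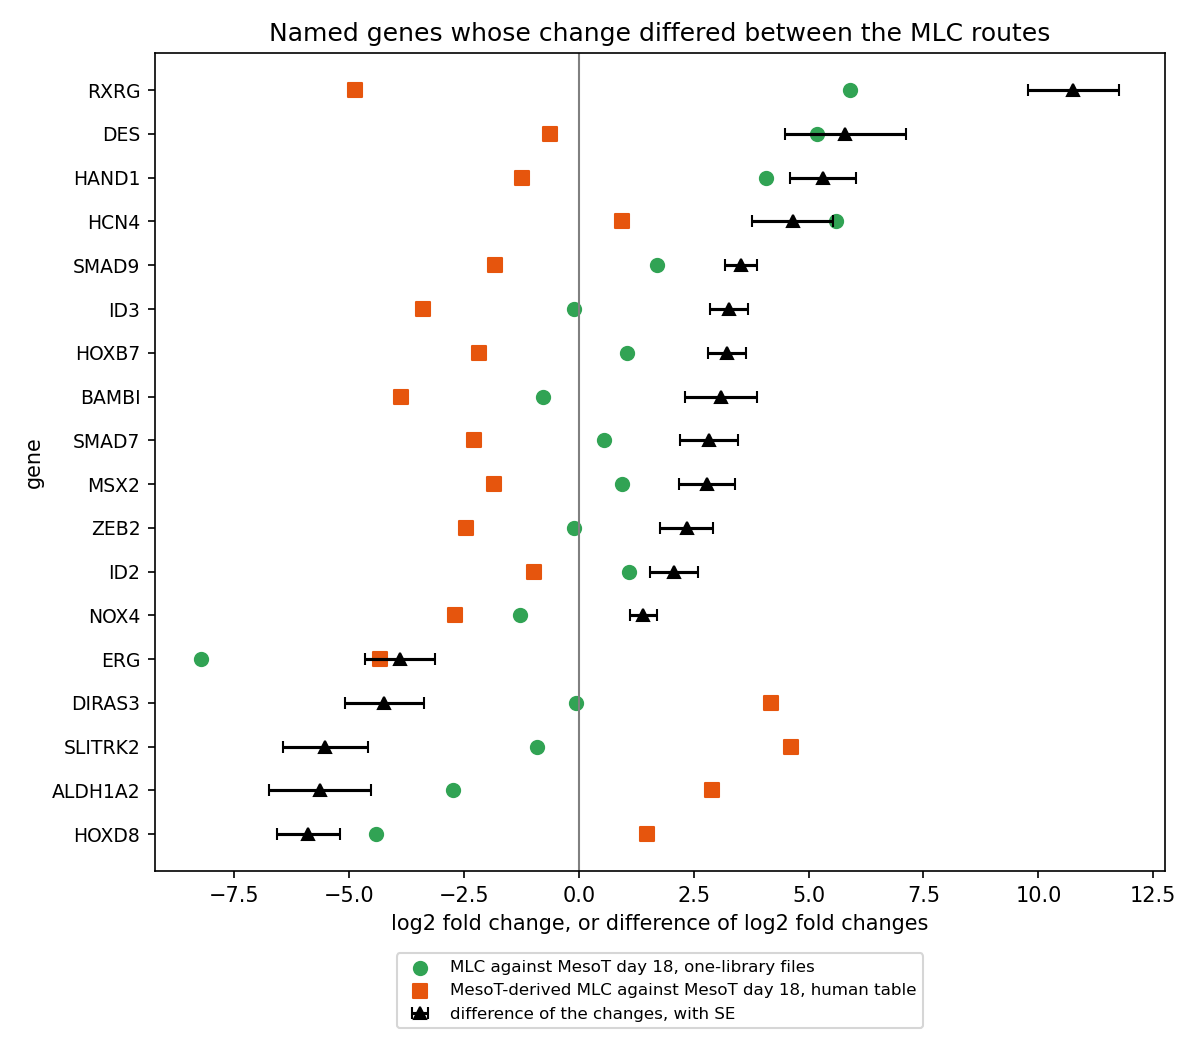
Log2 fold change against MesoT day 18 of MLC (circles, one-library files) and MesoT-derived MLC (squares, human table), and the difference of these changes with its standard error (triangles), for 18 named genes counted alike that passed the test of the difference. ID3 had a difference of 3.28 and HOXD8 one of -5.88.

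Mouse Wt1-lineage cells were described by organ, without a replicate check. The labels and the column names of the counts give different embryonic days for the sorted cells. Of 19605 genes, those with a log2 CPM of at least 5 in an organ could count as higher there. At least 4-fold higher than the mean of the other organs were 278 in heart, 98 in lung, 122 in liver and 73 in gut. At least 4-fold lower were 78, 33, 32 and 39 genes with a mean log2 CPM of at least 5 in the other organs. The files give Ensembl IDs without names. ENSMUSG00000029368 had 56215 counts in liver and 13 in the other organs together, and ENSMUSG00000044220 had 1300 in gut and 17 in the others. The highest ratio in heart was that of ENSMUSG00000013936, with 1817 counts against 1 in the others. In lung it was that of ENSMUSG00000022097, with 1769 against 2. Which cells these counts come from was not tested. ENSMUSG00000064325 had 3 counts in heart and 18908 in the others, and ENSMUSG00000031965 had 29 in gut and 13992 in the others. Across genes, Spearman's rho was highest between lung and gut (0.963) and lowest between heart and liver (0.922). Among genes with a log2 CPM of at least 5 in either organ, 468 lay at least 4-fold apart between heart and lung. Between lung and gut these were 169.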

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

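All tests in this part were chosen after the results were seen: the test of the difference between the changes of both MLC routes, and each test of an explanation. The results given first are differences between groups, namely list and gene changes from MesoT day 18 that differed between MLC and MesoT-derived MLC. Each change is taken within its own set of files, so a difference in counting between the sets that acts equally on both groups of a set cancels. A technical difference of the MLC libraries alone would not cancel. Both sets hold the same labelled MesoT day 18 samples, which this test entered as separate libraries. Its errors and p-values do not reflect that they are shared.

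The change of BMP response genes from MesoT day 18 differed between the MLC routes. The list's difference had camera adjusted p = 4.59e-08 with a median of 2.72 log2, 7 of 16 genes past the threshold and 0 the other way, and adjusted p = 0.166 with an estimated correlation. In log2 units of the MLC change minus the MesoT-derived change, the differences were BAMBI (3.10 ± 0.79), HAND1 (5.31 ± 0.71), ID2 (2.08 ± 0.52), ID3 (3.28 ± 0.41), MSX2 (2.79 ± 0.61), SMAD7 (2.84 ± 0.63) and SMAD9 (3.54 ± 0.34). HAND1, SMAD9 and ID2 were higher than day 18 in MLC, at 4.08, 1.71 and 1.098, whereas in MesoT-derived MLC they lay at -1.24, -1.83 and -0.98. Among other named genes counted alike, DES (5.80), HCN4 (4.65), HOXB7 (3.22), ZEB2 (2.35) and NOX4 (1.4) had a higher change in the MLC route. RXRG had the largest difference, 10.76, but held 3 counts over the MesoT-derived MLC libraries, so this fitted value depends on the prior count. HOXD8 (-5.88), ALDH1A2 (-5.63), SLITRK2 (-5.51), DIRAS3 (-4.23) and ERG (-3.89) had a lower change in the MLC route. Of 24967 genes 2383 passed this test, and 952 of the 12732 counted alike.

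Named antisense genes were lower in MLC than in MesoT day 18, with 470 of 1016 called lower and 15 higher. Over named pairs of a gene and its antisense partner, antisense counts were 7.20% and 7.88% of the partner's at day 18 in the one-library files, 2.52% and 2.59% in MLC, and 2.37% and 3.52% at day 18 in the human table. With the day 18 counts of the human table, the median over 941 antisense genes was -0.40 (quartiles -2.67 and 0.77), against -2.10 before over the 849 genes in both fits. Of these 849, 411 were called lower and 13 higher before, 192 and 115 after, and 132 lower in both fits. A lower antisense level shared by mesothelium-like cells is argued against by the median of -0.19 (quartiles -0.65 and 0.30) over 676 genes in MesoT-derived MLC, while a difference in library preparation or counting of MLC may contribute, and the call for any single antisense gene stays uncertain.

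MesoT replicates 1 and 2 differed in the same genes at day 18 and day 22. H19, an imprinted non-coding gene, had 252180 and 110 counts at day 18 and 191713 and 190 at day 22 in the human table, and 219466 and 91 at day 18 in the one-library files. Among all genes past the low-count filter, 937 were over 4-fold apart at day 18 in the human table. Of these, 87.2% lay on the same side at day 22, which argues against counting noise. The counting of one set is argued against too, since 99.4% of 852 such genes lay on the same side in the one-library files. The design names no biological difference between the replicates, so none was tested, and a difference between starting cultures or lines of culture may remain.

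Hepatocyte and gut epithelium genes were higher in both MLC routes. Whether a technical difference of the MLC or MesoT-derived MLC libraries contributes was not tested here, so it stays open. RNA from hepatocyte-like cells may add to these counts, but 5 of 10 abundant liver transcripts called higher in both routes does not decide it. AFP was at 59.4 CPM in MLC and 65.8 in MesoT-derived MLC, ALB at 1.30 in MLC, and the hepatocyte list holds most of these transcripts. For RNA from endoderm cells 1 of 9 endoderm factors, HNF4A, was called higher in both, where most factors lay under 5 CPM, too low to decide; no sort is named for these cells.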

How the results depend on the processing

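The settings varied here were chosen before the data were examined; the fits on genes counted alike, those through MesoT day 18 in each set and those without the smooth muscle library were chosen after. Of 331 named gene results 265 passed the threshold, 133 of them kept their call and direction in every alternative run, 129 lost the call in at least 1 and 4 changed sign in at least 1, with overlap. The cause was not tested unless stated. Calls gained in an alternative run are not in these counts.

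For MLC against MesoT day 18 (5666 genes), the count was 9237 with the day 18 counts of the human table, where BEST1 changed sign to 0.09, and 993 in a fit of genes counted alike alone, against 2257 called among such genes in the fit over all genes, so testing fewer genes does not by itself account for the drop; leaving out 1 library gave 1714 to 6601. For MesoT FCS against MesoT day 18 (6301) it was 3253 with only the groups compared, where fewer samples set the spread, 12757 with the human table's day 18, and 2783 to 7845 leaving out 1 library. For MLC against MesoT FCS (11272) it was 6133 on genes counted alike and 4962 to 8507 leaving out 1 library. For MesoT-derived MLC against MesoT (2219) it was 4604 by DESeq2, 1092 on genes counted alike, 380 against day 18 alone, 612 against day 22 alone, and 0 to 2995 leaving out 1 library. For day 22 against day 18 it stayed 0 by edgeR, DESeq2 and limma voom and leaving out each library, with 171 genes at an unadjusted p under 0.05. For smooth muscle (1998) it was 4925 by DESeq2 and 2339 to 4292 leaving out 1 MesoT day 18 library; leaving out its only library gives no comparison. For MLC against MesoT-derived MLC (10335) it was 2592 on genes counted alike and 6237 to 7289 leaving out 1 library. Taken through MesoT day 18 it was 2383, with PIK3R2 at 0.16, NBPF20 at 1.39 and UPK1B at 3.41, reversed. Where leaving out a library left 1 in a group, that library was assumed to vary like the other groups.

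With an estimated correlation 0 lists were called in each comparison, against 7, 11, 11, 10, 4, 8 and 3 in the order above. On genes counted alike 6 lists were called for MesoT FCS against MesoT day 18 and 1 for the MLC routes. Genes higher in both MLC routes numbered 153 against day 22 alone and 121 on genes counted alike against day 22 alone, from 425. With the day 18 replicates split an overlap could not arise, since that fit made no call for MesoT-derived MLC. For the library labelled smooth muscle, the correlation with MesoT day 18 minus that with MLC was 0.066 over all genes, 0.436 over 500 genes and 0.394 with a prior count of 0.5, from 0.375, and minus that with MesoT FCS 0.017 over all genes, from 0.074. This contrast was defined after the data were seen.

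The replicate numbers are not stated to pair the samples. Correlations of same-numbered deviations were 0.557 between MesoT day 18 and day 22 and -0.0636 to 0.0730 otherwise. With 2 replicates per group and no stated pairing, the block appears here only. With the replicate number as a block the count was 527 for smooth muscle, 4652, 5601, 10407, 2800, 0 and 10195 for the other comparisons in the order above, and 8 lists were called for day 22 against day 18, with the mesenchymal (0.0296), contractile (0.0296), TGF-beta response (0.0394) and lateral plate (0.0394) lists added (camera adjusted p). Depth limits genes under 3 counts per group, and 2-fold changes were mostly missed in simulations. The human to mouse rank correlation with its alternatives and the mouse gene lists were not run, since the reference used here names human genes only.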

Other observations

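The library labelled smooth muscle held genes of stratified epithelium, a list chosen after its values were seen. Since the list was picked for this pattern, it was not used as a test. KRT5 lay at 870 CPM against 0.154, KRT16 at 628 against 0.114, KRT14 at 259 against 0.0825 and COL17A1 at 544 against 1.93, and KRT1 was at least 281-fold higher. Of its 19 genes DSC3 (0.97) and KRT10 (0.18) did not pass. None of the 19 was called in MLC against MesoT day 18, and of 14 tested in MesoT-derived MLC 1 was higher and 1 lower. These levels leave open whether the library is smooth muscle alone. No explanation was tested, and 1 library has no replicate check.

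Some called lists belong to pictures already given, and some were called only on genes counted alike. The latter all pointed down: neural genes in MLC against MesoT day 18 (camera adjusted p = 0.271 over all genes, 0.0103 on genes counted alike), matrix genes (0.0741, 0.0326) and SRF and YAP targets (0.0741, 0.0276) in MLC against MesoT FCS, and WNT response in MesoT-derived MLC against MesoT (0.195, 0.0159). In MesoT FCS against MesoT day 18, 4 of 9 epicardial genes were lower (camera adjusted p = 0.0334, adjusted p = 0.550 with an estimated correlation), as were 3 of 14 anterior HOX genes (camera adjusted p = 0.0375, 0.719 with an estimated correlation); on genes counted alike neither list was called (camera adjusted p = 0.0551 and 0.0782). In MLC against MesoT FCS, 5 of 9 epicardial genes were higher (camera adjusted p = 0.00924, 0.447 with an estimated correlation), as were 12 of 13 hepatocyte genes (camera adjusted p = 0.000729, 0.662) and 8 of 11 gut epithelium genes, with 1 lower (camera adjusted p = 0.0122, 0.662). In the library labelled smooth muscle against MesoT day 18, 0 of 20 cholesterol synthesis genes were called by edgeR while camera pointed up (adjusted p = 0.00595, 0.717 with an estimated correlation), and 2 of 20 interferon response genes were lower (camera adjusted p = 0.0388, 0.717 with an estimated correlation).

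Libraries also differed outside the comparisons. Mitochondrial genes took 6.84% and 7.76% of counts in the MLC libraries and between 2.48% and 3.42% in the other one-library files. Genes above a minimum mean level were compared between replicates. In the one-library files, 688 were over 4-fold apart at MesoT day 18, 390 in MesoT FCS and 10 in MLC. In the human table these were 569 at day 18, 264 at day 22 and 238 in MesoT-derived MLC. Among other imprinted genes looked at in the human table, DLK1 had 14446 and 1913 counts in MesoT replicates 1 and 2 at day 18 and NNAT 571 and 52, whereas IGF2 had 101789 and 122080 and MEG3 53 and 71. These genes were picked after their values were seen.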
